A study of Mus musculus with 16 samples.

How the data were processed

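RNA from 16 disc tissue samples was measured on 1-colour Affymetrix arrays, with 4 arrays each for NP CTR, NP cKO, AF CTR and AF cKO. Per the labels, NP and AF were micro-dissected from lumbar and tail discs and pooled per animal, RNA was purified with RNeasy columns, and biotin-labelled targets were made with the GeneChip WT Plus kit. Per the labels, the deposited values are log2 signals made by signal space transformation RMA (sst-RMA) in Transcriptome Analysis Console, whose version is not given in the sources used here. The labels also name a detection p under 0.05, a p under 0.05 and a fold of at least 1.75, and those filters had not been applied to the deposited table.

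The table holds 28846 probe sets, of which 6640 control probe sets were left out and 22206 were tested. Of these, 19572 carry 1 gene symbol, for 19505 genes, and 2634 carry none. The values run from 2.57 to 19.93. As a measure of background, 5222 negative control probe sets had medians per array from 6.14 to 6.59, close to the median probe set mean of 6.76, so that dim genes cannot be separated from background and no detection call was used. No change was made to the normalization of the deposited values.

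The arrays were fitted with limma 3.58.1 in R 4.3.3 as 4 group means on the log2 values, with the default moderation of the spread. The comparisons were cKO minus CTR in NP, the same in AF, the difference of these changes, and NP minus AF in CTR. A probe set counts as changed at a Benjamini-Hochberg adjusted p under 0.05 over all 22206 probe sets. On simulated data with 100 changes of each size, changes of log2 size 1 were recovered in 45% (NP) and 40% (AF) of cases and those of size 2 in 96% and 93%, with 12 false calls among 153 and 15 among 148. The simulated noise was independent between probe sets and had the same SD in all 4 groups. It holds no signals shared by many genes on single arrays, so these rates may not apply to the real arrays.

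The comparisons, tests, naming rule and gene lists were fixed before the data were examined. Named genes are the 12 largest rises and the 12 largest falls per genotype comparison among changed probe sets whose groups do not overlap, the 10 largest in each direction for NP against AF, Sox9, and up to 4 members per list with the smallest p. Where under 5 pass, the 10 smallest p are named as not passing. Predicted genes are counted but not named, and a gene with several probe sets is represented by the one with the highest mean.

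The 35 lists, with 843 of 924 genes measured, cover cartilage matrix and Sox9 targets, notochordal, AF and tendon markers, matrix enzymes and inhibitors, glycosaminoglycan and collagen synthesis, stress, signalling, cell cycle, metabolism, and markers of other cell types. Each was tested with camera of limma at its preset correlation of 0.01, and adjusted over 105 tests of 3 contrasts. The same test with the correlation estimated per list, and fry, were alternatives.

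Alternatives fixed before the data were examined were median centring, a second quantile normalization, a filter on dim probe sets, 1 probe set per gene, an intensity trend, array weights, the thresholds of the labels, the 8 arrays of the tissue alone, blocks for animal or replicate number, and leaving out each array. Leaving out AF cKO replicates 2 and 4, leaving out AF CTR replicate 1 and AF cKO replicate 3, and further settings for the list tests and the correlation were added after seeing the data. NP and AF with the same code in the sample titles come from 1 animal. Their deviations from the group means correlated with r from -0.293 to 0.348, with 3 of 8 pairs over 0.1, and the animal as a block was an alternative. Every other split of the 8 animals into 4 and 4, 35 in all with the real one, was fitted in the same way to see how often chance gives as many calls. For NP against AF the splits were of the 8 control arrays, which come from 4 animals and were treated as separate. Exact permutation tests compared the list scores of 4 and 4 arrays, where the smallest possible p is 0.0286.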

Results

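The expression of genes was measured in mouse intervertebral discs, in the gel-like nucleus pulposus (NP) at the centre and in the fibrous ring around it, the annulus fibrosus (AF). The 16 arrays came from 8 female mice of 3 to 4 months. In the 4 Sox9 control mice (CTR), both copies of Sox9 carry loxP sites and no Cre is named. The 4 conditional knockout mice (cKO) also carry a tamoxifen-inducible Cre driven by Acan, the aggrecan gene of cartilage-like cells. Tissue was taken 5 days after the first injection, and NP and AF of each animal gave 1 array each, so that each of the 4 groups holds 4 arrays. The labels name tamoxifen for the cKO mice and do not say whether the controls were injected, so an effect of the drug is not separated from that of the genotype here. The values are log2 signals of 22206 probe sets, and the median signal per array lay between 6.66 and 6.89. Arrays of one group correlated with r from 0.963 to 0.983 across probe sets, and NP with AF arrays from 0.891 to 0.957. The number of arrays limits the precision. Where an error follows a mean it is the SD with n = 4, and SE is that of a log2 change in the limma fit.

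In the NP, the comparison of cKO with CTR asks which genes respond within days to the loss of Sox9, the transcription factor that directs cartilage gene programmes. Sox9 itself fell by 6.51 (SE 0.30) on the log2 scale, from 16.27 ± 0.36 to 9.75 ± 0.25, which is 91.4-fold (adjusted p = 3.1e-10). Its signal was 16.19, 16.14, 16.79 and 15.95 in NP CTR replicates 1 to 4, and 9.69, 9.55, 10.12 and 9.65 in NP cKO replicates 1 to 4. In the AF it was 17.25, 17.45, 16.59 and 16.39 in CTR, and 12.10, 11.43, 12.99 and 12.44 in cKO, in the same order. Where the Sox9 probes lie relative to the deleted exons is not known from the labels. Gjc3, a gap junction connexin, fell by 4.30 (SE 0.43), and Kcnip3, a calcium-binding modulator of potassium channels, fell by 3.46 (SE 0.34), each with an adjusted p of 4.9e-05. The Kcnip3 signal of 6.50 in NP cKO lies at the background, where the negative control medians per array reach 6.59, so its fall is a lower bound. Plekhb1, a membrane-associated pleckstrin homology protein, fell by 3.00 (SE 0.33, adjusted p = 1.8e-04). Altogether 27 probe sets changed at an adjusted p under 0.05, and all 27 fell.

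Among the other NP genes that fell were Meltf, an iron-binding surface protein (by 2.94, SE 0.43, adjusted p = 0.00461), and Cd36, a receptor that takes up fatty acids (by 2.55, SE 0.39, adjusted p = 0.00707). Tmod2, which caps actin filaments, fell by 2.19 (SE 0.31, adjusted p = 0.00312), and Dhrs3, a reductase of retinaldehyde, fell by 1.75 (SE 0.23, adjusted p = 0.00113). Trpm4, a calcium-activated cation channel, fell by 1.88 (SE 0.29, adjusted p = 0.00875). Genes of lysosomes and endosomal sorting also fell: the lysosomal mannosidase Man2b1 by 2.95 (SE 0.50, adjusted p = 0.0220), the retromer subunit Vps35 by 1.80 (SE 0.34) and the sorting nexin Snx10 by 1.84 (SE 0.35), the last with an adjusted p of 0.0399 that Vps35 shared. These 3 genes are placed together from general knowledge, since no list for lysosomes was tested. Of the glial-type genes outside the naming rule, chosen after their values were seen, S100b fell by 1.46 (SE 0.26) and Sh3tc2, a gene of Schwann cells, by 1.66 (SE 0.29), each with an adjusted p of 0.0277. The nerve and Schwann cell list as a whole was not called in the NP, with 8 of 17 members higher, 9 lower and a median of -0.04 (adjusted p = 0.657). The Sh3tc2 signal in NP cKO, 5.78, lies under the negative controls, so its fall is a lower bound. In all 27 probe sets the 4 cKO values lay below the 4 CTR values. Groups that do not overlap, in either direction, are given by chance in 2.86% of probe sets and were found in 2.93% of all probe sets in the NP.

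Across the NP, 1018 probe sets had an unadjusted p under 0.05, where chance gives 1110.3, and 262 passed the thresholds of the labels (unadjusted p under 0.05 and a fold of at least 1.75), 74 higher and 188 lower. The count of 27 fell to 16 without NP CTR replicate 1, 17 without CTR replicate 2, 10 without CTR replicate 3, 16 without CTR replicate 4, 13 without cKO replicate 1 and 17 without cKO replicate 2, each a fit on fewer arrays. Gjc3, Kcnip3, Plekhb1, Meltf, Cd36, Tmod2 and Dhrs3 kept their calls without any 1 of the 8 NP arrays. Trpm4 lost its call without CTR replicate 3 (adjusted p = 0.0542). Man2b1 lost it without CTR replicates 2, 3 or 4 or cKO replicate 1 (adjusted p up to 0.141). Vps35 lost it without any of CTR replicates 2 to 4 or cKO replicates 1, 2 or 4 (adjusted p up to 0.202), and Snx10 without any array but cKO replicate 3 (adjusted p up to 0.208).

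**Figure D1:**
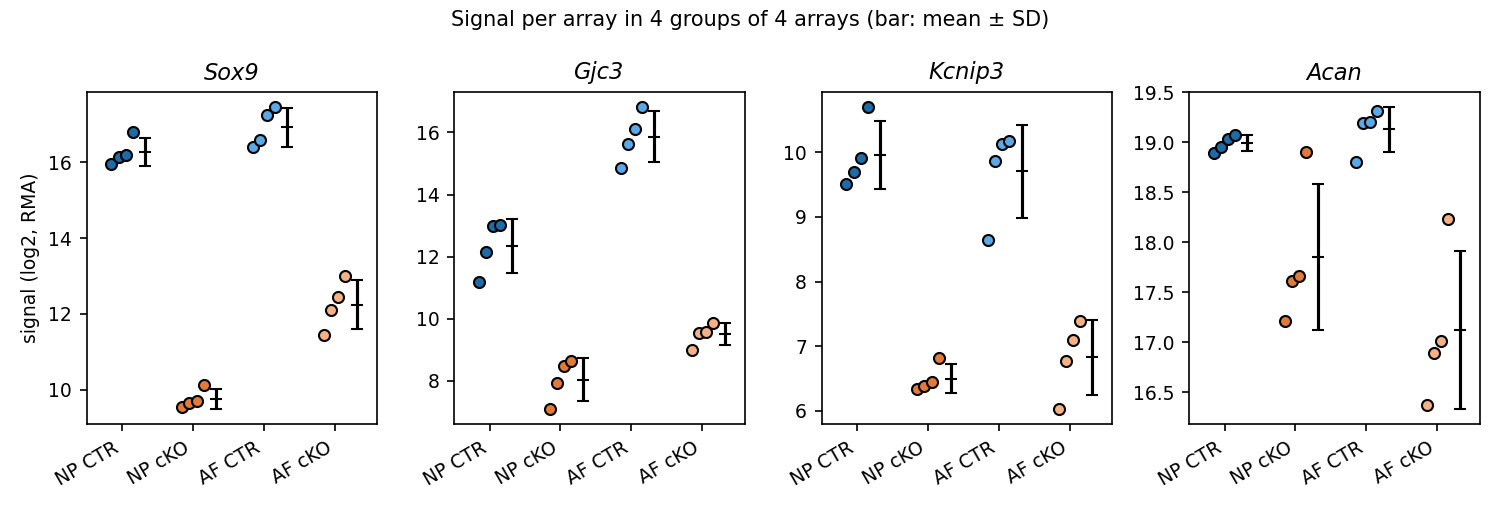
Log2 signal of Sox9, Gjc3, Kcnip3 and Acan on each of the 16 arrays, in 4 groups of 4 arrays, with the mean and SD of each group beside the points. In Gjc3 the group means are 12.33 and 8.03 in NP CTR and cKO, and 15.86 and 9.5 in AF CTR and cKO.

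The gene lists fixed before the data were examined were tested against all other probe sets with camera. In the NP, cartilage matrix and Sox9 target genes fell as a group, with a median change of -0.19 over 30 measured members (adjusted p = 9.5e-04). With an estimated correlation the adjusted p = 0.574. The mean signal of the list went against the fall in NP cKO replicate 4, at 9.37, above all NP CTR arrays (8.59 to 8.93), and was 8.11, 8.07 and 8.44 in NP cKO replicates 1 to 3. No member passed over all genes and 7 fell when adjusted over the list alone, among them the growth factor receptor gene Fgfr3 (-1.92, SE 0.41), Hapln1, which links aggrecan to hyaluronan (-1.83, SE 0.42), and Acan (-1.14, SE 0.34). Interferon response genes also fell as a group, with 20 of 27 members lower and a median of -0.31 (adjusted p = 4.8e-04, adjusted p = 0.565 with an estimated correlation). No member passed, alone or over all genes, and Ifit3 changed by -1.04 (SE 0.29) with an unadjusted p of 0.00220. The mean interferon signal was 7.52 in NP CTR replicate 3 and from 6.92 to 7.11 in the other NP CTR arrays. In NP cKO it ran from 6.53 to 7.05, so the groups overlap. Without NP CTR replicate 3 the call was kept (adjusted p = 0.0371).

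Genes of TGF-beta and BMP signalling rose as a group in the NP, with a median of 0.27 over 45 members (adjusted p = 7.4e-04, adjusted p = 0.565 with an estimated correlation). Adjusted over the list alone, Tgfb1, a ligand of the pathway, was higher by 1.75 (SE 0.46) and Bmp5 lower (-1.21, SE 0.33). The call was lost without NP cKO replicate 2 (adjusted p = 0.0600) or cKO replicate 4 (adjusted p = 0.0501). Hypoxia and glycolysis genes rose as a group, with 27 of 33 members higher and a median of 0.16 (adjusted p = 0.00914, adjusted p = 0.741 with an estimated correlation). This call was lost without NP CTR replicate 2 (0.0887), CTR replicate 4 (0.111), cKO replicate 2 (0.364) or cKO replicate 3 (0.303), given as adjusted p. Markers of AF and tendon had a median change of 0.27 in the NP (adjusted p = 0.0594), and 1 array stood apart: the mean signal of that list was 9.49 in NP cKO replicate 4 and at most 8.49 in the other NP cKO arrays. The small proteoglycan gene Dcn, abundant in fibrous tissue, reached 18.97 in that array and 14.12 in NP cKO replicate 3.

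Beyond these 4 lists, 31 lists had adjusted p from 0.0594 to 0.860 in the NP. They included notochordal and NP markers (median -0.09, adjusted p = 0.383), apoptosis genes (-0.01, 0.720), matrix degrading enzymes (0.03, 0.643) and inflammatory mediators (-0.001, 0.810). In glycosaminoglycan synthesis (-0.08, 0.222), the sulfate transporter gene Slc26a2 fell by 1.34 (SE 0.24, adjusted p = 0.0277), a call lost without CTR replicates 2, 3 or 4 or cKO replicates 1, 3 or 4 (adjusted p up to 0.164). In pericyte and smooth muscle markers, the smooth muscle myosin gene Myh11 fell by 1.66 (SE 0.26, adjusted p = 0.00875). Tagln (2.64, SE 0.74) and Acta2 (1.86, SE 0.61), both actin-associated genes of contractile cells, rose when adjusted over the list alone. The median of that list was -0.06, whereas its mean was 0.27 and its test pointed up (adjusted p = 0.560). The test and the median also differed in sign for endoplasmic reticulum stress, Wnt signalling, autophagy and inflammatory genes in the NP.

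In the AF, the same comparison gave the largest fall in Gjc3, by 6.36 (SE 0.43) from 15.86 ± 0.82 to 9.5 ± 0.36, which is 81.9-fold (adjusted p = 1.1e-07). Sox9 fell by 4.68 (SE 0.30) from 16.92 ± 0.51 to 12.24 ± 0.65, 25.7-fold (adjusted p = 1.1e-07). Cartilage genes fell: Acan, which encodes aggrecan, by 2.0 (SE 0.34, adjusted p = 0.0218), the cartilage matrix gene Ucma by 3.48 (SE 0.62, adjusted p = 0.0269) and Fgfr3 by 2.50 (SE 0.41, adjusted p = 0.0151). The Acan signal of the controls, 19.13 ± 0.22, lies near the highest value of the arrays, 19.93. Altogether 22 probe sets changed at an adjusted p under 0.05, 3 higher and 19 lower. In all 22 the 4 cKO values lay on one side of the 4 CTR values, which chance gives in 2.86% of probe sets and which held for 4.33% of all probe sets.

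Other genes that fell in the AF were Meltf (by 3.45, SE 0.43, adjusted p = 6.6e-04), Kcnip3 (by 2.88, SE 0.34, adjusted p = 4.9e-04), Plekhb1 (by 2.37, SE 0.33, adjusted p = 0.00328) and Slc26a2 (by 1.59, SE 0.24, adjusted p = 0.00728). Ppp1r1b, an inhibitor of a protein phosphatase, fell by 2.71 (SE 0.32, adjusted p = 4.9e-04), and Scin, which severs actin filaments, fell by 2.45 (SE 0.30, adjusted p = 6.6e-04). Receptors and signalling genes included the adhesion receptor Adgrg6, which fell by 2.35 (SE 0.39, adjusted p = 0.0163), the secreted Wnt inhibitor Sfrp5 by 2.15 (SE 0.36, adjusted p = 0.0191) and the receptor-like Fgfrl1 by 1.51 (SE 0.27, adjusted p = 0.0244). The hormone gene Stc2 fell by 1.70 (SE 0.32, adjusted p = 0.0472). The 3 genes that rose were Thsd4, a protein of the extracellular matrix, by 2.51 (SE 0.39, adjusted p = 0.0103), the stress-induced Nupr1 by 1.42 (SE 0.25, adjusted p = 0.0269), and Dmtn, which binds actin in the red cell membrane, by 1.19 (SE 0.22, adjusted p = 0.0384). Both Dmtn means, 5.28 in CTR and 6.47 in cKO, and the CTR mean of Thsd4, 6.35, lie under the highest negative control median of 6.59, so the rise of Thsd4 is a lower bound.

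The AF count depended on single arrays. Of 2359 probe sets with an unadjusted p under 0.05, 1096 were higher and 1263 lower, and 774 passed the thresholds of the labels, 456 higher and 318 lower. The count of 22 became 142 without AF CTR replicate 1 (99 higher, 43 lower), 112 without AF cKO replicate 4 (80 higher, 32 lower), 58 without AF CTR replicate 3, and 12 without AF cKO replicate 1 or replicate 2. Leaving out AF cKO replicates 2 and 4, chosen after seeing their muscle marker signals, gave 34 (21 higher, 13 lower), of which 10 were among the 22. Leaving out AF CTR replicate 1 and AF cKO replicate 3, chosen after seeing their osteoclast marker signals, gave 112 (76 higher, 36 lower), of which 20 were among the 22. A fit on the 8 AF arrays alone called 8, and a second quantile normalization gave 37.

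Without any 1 AF array, Gjc3, Meltf, Kcnip3, Ppp1r1b, Scin, Plekhb1, Slc26a2 and Thsd4 kept their calls. Under every alternative only Gjc3 and Meltf of these did so. Each of the others lost its call under at least 1 other alternative, with a highest adjusted p from 0.0712 (Kcnip3) to 0.261 (Thsd4). The SEs pool the spread of the NP and AF arrays. For Ppp1r1b the SD was 0.17 and 0.28 in NP CTR and cKO, and 0.90 and 0.24 in AF CTR and cKO. For Gjc3 it was 0.87 and 0.68, and 0.82 and 0.36. For Ucma it was 0.50 and 0.36, and 1.71 and 1.12, so its pooled SE understates the AF spread. Acan lost its call without CTR replicates 2 or 4 or cKO replicates 1 or 3 (adjusted p up to 0.0689), and Fgfr3 without cKO replicate 1 or 2 (up to 0.0602). Ucma lost it without CTR replicate 2 or cKO replicates 1 or 2 (up to 0.152). Adgrg6 and Fgfrl1 lost theirs without the same 3 arrays (up to 0.0626 and 0.0990), and Sfrp5 without CTR replicate 4 or cKO replicates 1 or 2 (up to 0.0711). Nupr1 lost it without CTR replicate 4 or cKO replicates 1 to 3 (up to 0.152). Stc2 lost it without CTR replicates 2 or 4 or cKO replicates 1 to 3 (up to 0.207), and Dmtn without CTR replicates 2 to 4 or cKO replicates 1 to 3 (up to 0.206). These maxima, from Acan to Dmtn, cover only omissions of 1 array. Over all alternatives the highest adjusted p of these genes ran from 0.175 (Acan) to 0.371 (Ucma).

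Cartilage matrix and Sox9 target genes fell as a group in the AF, with a median change of -1.20 over 30 members, 23 of them lower (adjusted p = 4.9e-13, adjusted p = 0.565 with an estimated correlation). Over all genes Fgfr3, Acan and Ucma fell, and 18 fell when adjusted over the list alone, among them Papss2, which makes the sulfate donor for proteoglycans (-2.73, SE 0.53). The mean signal of this list was 11.32, 11.16, 11.61 and 10.79 in AF cKO replicates 1 to 4, and 13.43, 12.69, 11.41 and 12.03 in AF CTR replicates 1 to 4, so that CTR replicate 3 lay within the cKO range (exact permutation p = 0.0571, adjusted p = 0.229 over 8 lists). Col10a1, a collagen of hypertrophic cartilage, followed the order of the list among the AF CTR arrays. It was 17.40, 14.26, 9.47 and 11.71 in AF CTR replicates 1 to 4, and from 9.79 to 12.35 in AF cKO. Whether the cartilage content of the control samples adds to the fall was not tested. Glycosaminoglycan synthesis genes also fell as a group (median -0.11 over 32 members, adjusted p = 0.0171, adjusted p = 0.565 with an estimated correlation), with Slc26a2 passing over all genes and 5 lower when adjusted over the list alone. The latter call was lost without AF CTR replicate 1 (adjusted p = 0.0652), CTR replicate 2 (0.213) or cKO replicate 1 (0.0846).

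Markers of neutrophils, red cells, macrophages and endothelium rose as groups in the AF of cKO mice, while those of lymphocytes and osteoclasts were not called. All 20 neutrophil and granulocyte markers were higher, with a median of 2.48 (adjusted p = 4.1e-18, adjusted p = 0.565 with an estimated correlation). None passed over all genes and 16 rose when adjusted over the list alone, among them the granule protein genes Camp (2.33, SE 0.53) and Ltf (3.03, SE 0.77), whose CTR means of 4.97 and 6.32 lie under the negative controls. The mean signal of the list in the AF cKO arrays was 10.07, 9.99, 11.21 and 8.18 in replicates 1 to 4, and in the AF CTR arrays it was 9.77, 6.97, 6.06 and 6.68, so that CTR replicate 1 lay within the cKO range. Erythroid markers rose (median 0.91 over 13 members, adjusted p = 1.9e-06, adjusted p = 0.565 with an estimated correlation), with 5 higher when adjusted over the list alone, Car2 (2.80, SE 0.70) and the haem synthesis gene Alas2 (1.46, SE 0.47) among them. The mean erythroid signal was 8.61 in AF cKO replicate 3 and 7.72, 7.33 and 6.67 in replicates 1, 2 and 4, and 2 AF CTR arrays lay in this range. Macrophage and monocyte markers rose (median 0.58 over 24 members, adjusted p = 7.3e-06, adjusted p = 0.565 with an estimated correlation), with 3 higher when adjusted over the list alone, Ly6c2 (2.57, SE 0.53) and the lysozyme gene Lyz2 (3.08, SE 0.90) among them. The mean signal of that list in AF CTR replicate 1, 8.11, lay above AF cKO replicates 1, 2 and 4 (7.79, 7.75 and 6.85) and below replicate 3 (8.38). Endothelial markers rose (median 0.46 over 20 members, adjusted p = 5.4e-04, adjusted p = 0.565 with an estimated correlation) with no member passing. Their mean signal was 7.80 in AF CTR replicate 1, and 7.61, 7.59, 7.94 and 6.95 in AF cKO replicates 1 to 4, so the groups overlap. B and T lymphocyte markers had a median of -0.12 (adjusted p = 0.643), and osteoclast markers one of 0.31 (adjusted p = 0.201).

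Skeletal muscle markers rose as a group in the AF (median 1.16 over 26 members, adjusted p = 2.2e-14, adjusted p = 0.565 with an estimated correlation), and 19 rose when adjusted over the list alone. The mean signal of this list was 9.53 and 9.23 in AF cKO replicates 2 and 4, 6.83 and 6.42 in replicates 1 and 3, and from 6.33 to 7.18 in AF CTR. The myosin gene Myh2 reached 12.48 in cKO replicate 2 and 10.97 in replicate 4. Without these 2 arrays the adjusted p of the list was 0.710. Cell cycle genes rose as a group, with 28 of 29 members higher and a median of 0.72 (adjusted p = 3.6e-12, adjusted p = 0.565 with an estimated correlation), the mitotic kinase gene Plk1 (1.37, SE 0.42) among them, and no member passed alone. Their mean signal was highest in AF cKO replicate 3 (8.46), which also had the highest neutrophil and erythroid signals.

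**Figure D2:**
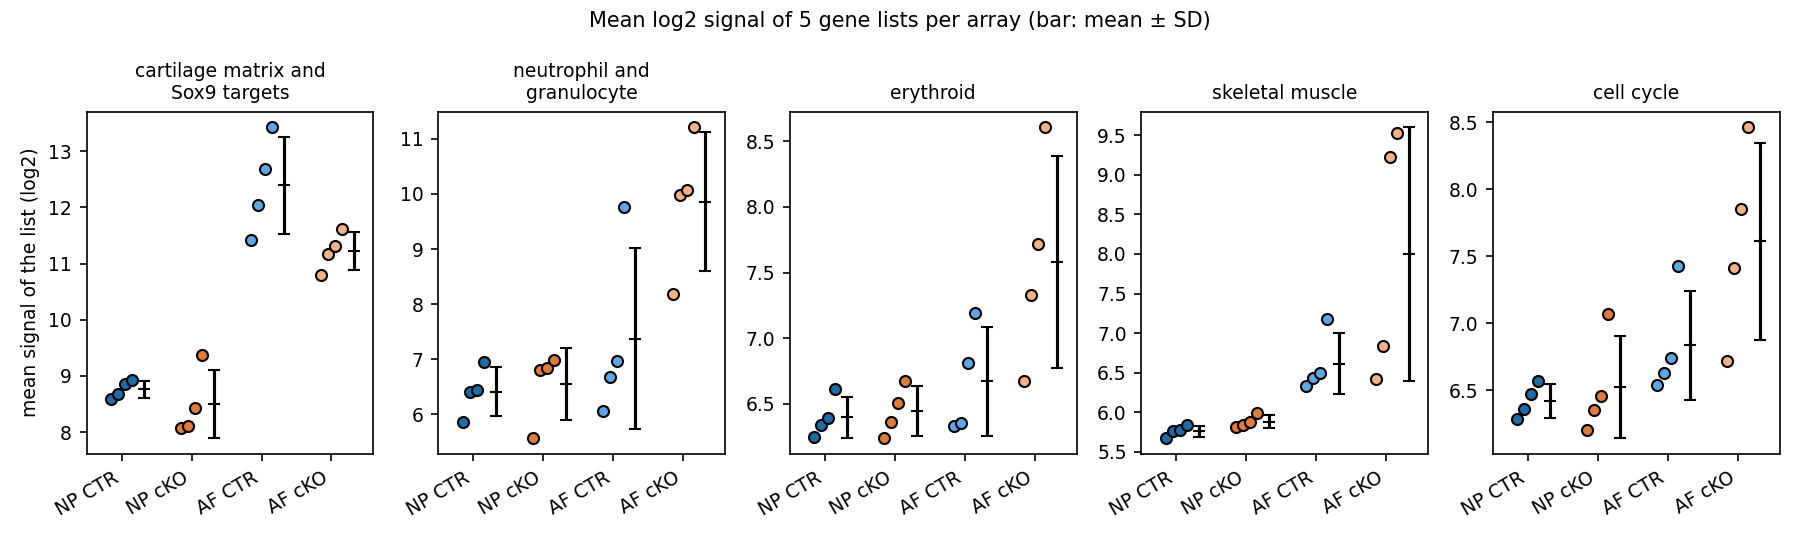
Mean log2 signal of 5 gene lists on each of the 16 arrays, in 4 groups of 4 arrays, with the mean and SD of each group beside the points. The neutrophil list spans 8.18 to 11.21 in AF cKO and 6.06 to 9.77 in AF CTR, and the muscle list is at 9.53 and 9.23 in 2 AF cKO arrays.

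Further lists that rose as groups in the AF were smaller in size. AF and tendon markers rose (median 0.44 over 22 members, adjusted p = 7.0e-04, adjusted p = 0.565 with an estimated correlation), with the collagen genes Col5a1 (1.30, SE 0.37) and Col3a1 (2.42, SE 0.70) higher when adjusted over the list alone, and the call was lost without AF cKO replicate 3 (adjusted p = 0.0508). Matrix degrading enzymes rose (0.33 over 30 members, adjusted p = 0.0203, adjusted p = 0.565 with an estimated correlation), with the neutrophil collagenase Mmp8 (2.62, SE 0.65) and the aggrecanase Adamts5 (1.17, SE 0.30) higher when adjusted over the list alone. That call was lost without AF CTR replicate 3 (0.201), CTR replicate 4 (0.0947), cKO replicate 1 (0.0612) or cKO replicate 3 (0.238). Autophagy genes (0.21 over 27 members, adjusted p = 9.9e-04) and cholesterol synthesis genes (0.19 over 19 members, adjusted p = 0.00560) rose, each with adjusted p = 0.565 with an estimated correlation, the latter with Idi1 (0.77, SE 0.19) higher when adjusted over the list alone and lost without AF cKO replicate 3 (adjusted p = 0.0508). The autophagy call was lost without AF cKO replicates 2 and 4, which had the highest signals of that list at 10.28 and 10.25 (adjusted p = 0.151, mean change 0.12 in place of 0.24), and with a second quantile normalization (0.0500). That of AF and tendon markers was lost without AF CTR replicate 1 and AF cKO replicate 3 (0.0824).

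TonEBP and osmotic response genes rose (0.38 over 15 members, adjusted p = 0.0308, adjusted p = 0.565 with an estimated correlation). When adjusted over the list alone 4 were higher, such as Atp1b1 (0.83, SE 0.20), whose signals lie under the negative controls, and the osmosensitive channel gene Trpv4 was lower (-1.71, SE 0.36). The call was lost without AF CTR replicate 4 or without cKO replicates 1, 2 or 4 (adjusted p from 0.0533 to 0.0654). The p53 target genes rose (0.19 over 24 members, adjusted p = 0.0371, adjusted p = 0.565 with an estimated correlation), a call lost without AF CTR replicates 1, 3 or 4 or cKO replicates 2 or 4 (adjusted p up to 0.112). Hypoxia and glycolysis genes (0.27 over 33 members, adjusted p = 5.4e-04), TGF-beta and BMP signalling genes (0.21 over 45 members, adjusted p = 0.0332) and endoplasmic reticulum stress genes (0.21 over 30 members, adjusted p = 0.0348) rose, each with adjusted p = 0.639 with an estimated correlation. In the TGF-beta list the BMP antagonist Grem1 was lower (-3.19, SE 0.69) when adjusted over the list alone. The hypoxia call was lost without AF CTR replicate 1 (adjusted p = 0.0948). It was also lost without AF cKO replicates 2 and 4 (0.234), whose muscle signals stand apart and which had the highest hypoxia signals, 12.77 and 12.78. The TGF-beta call was lost without CTR replicates 1, 3 or 4 or cKO replicates 2 or 3 (up to 0.242), and the stress call without CTR replicates 3 or 4 or cKO replicates 2 or 3 (up to 0.252). Without AF cKO replicates 2 and 4 the calls of TonEBP (adjusted p = 0.149), p53 (0.276) and TGF-beta genes (0.0784) were lost too, and without AF CTR replicate 1 and AF cKO replicate 3 those of TGF-beta (0.185) and stress genes (0.197). The mean change without AF cKO replicates 2 and 4, in place of that with all arrays, was 0.11 in place of 0.30 for hypoxia, 0.10 in place of 0.18 for p53, 0.27 in place of 0.33 for TonEBP and 0.19 in place of 0.21 for TGF-beta genes, so the last pair lost their calls with little change in size and fewer arrays fitted. Other lists grew without these arrays, such as matrix degrading enzymes (0.76 in place of 0.39), erythroid markers (1.49 in place of 0.91) and macrophage markers (1.13 in place of 0.74). A second quantile normalization ended the calls of all 5 lists (adjusted p from 0.0797 to 0.445), and the filter on dim probe sets those of all but hypoxia (from 0.122 to 0.476).

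The 18 lists with no call in the AF had adjusted p from 0.0622 to 0.945. Apoptosis genes had a median of 0.07 over 41 members with no member passing (adjusted p = 0.0622). Notochordal and NP markers (-0.14, adjusted p = 0.343), hypertrophic chondrocyte genes (0.21, 0.438), interferon response genes (-0.06, 0.425), inflammatory mediators (-0.03, 0.776) and nerve and Schwann cell markers (-0.14, 0.382) were among them. So were Wnt signalling genes (-0.05, 0.382), FGF signalling genes (-0.09, 0.343) and estrogen response genes (-0.13, 0.697), which hold the changed genes Sfrp5, Fgfr3 and Fgfrl1, and Stc2. Protease inhibitors (-0.15, 0.438), collagen processing genes (0.01, 0.713), immediate early genes (0.17, 0.551), osteoblast and osteocyte markers (0.04, 0.945), pericyte and smooth muscle markers (0.02, 0.251), adipocyte markers (-0.15, 0.643) and epidermal keratinocyte markers (-0.25, 0.152) complete the set. The median and the test differed in sign for inflammatory mediators.

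Across the compartments, 7 genes fell in both NP and AF: Gjc3, Kcnip3, Meltf, Plekhb1, Slc26a2, Sox9 and Tubb2b, a tubulin gene, where 0.0231 would be shared if the calls were independent. The calls of NP and AF are not independent, since they share animals, the targeted gene and 1 estimate of the spread per probe set. The numbers for independence given here are therefore a reference and not a test. Of the 27 NP probe sets 26 had the same sign in the AF and 23 of these had an unadjusted p under 0.05 there. Of the 22 AF probe sets 19 had the same sign in the NP, and 11 had an unadjusted p under 0.05. Past the thresholds of the labels, 24 were higher in both compartments (1.52 if independent), 54 were lower in both (2.69 if independent) and 1 changed in opposite directions. Across all probe sets the NP and AF changes correlated with r = 0.157, where probe sets are not independent replicates. Without replicate 2 of every group r was -0.0638, and 7 of the 35 splits of the animals gave as high a correlation, so chance is not excluded. The overlap of 7 became 3 without replicate 1 of every group and 4 without replicate 3.

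**Figure D3:**
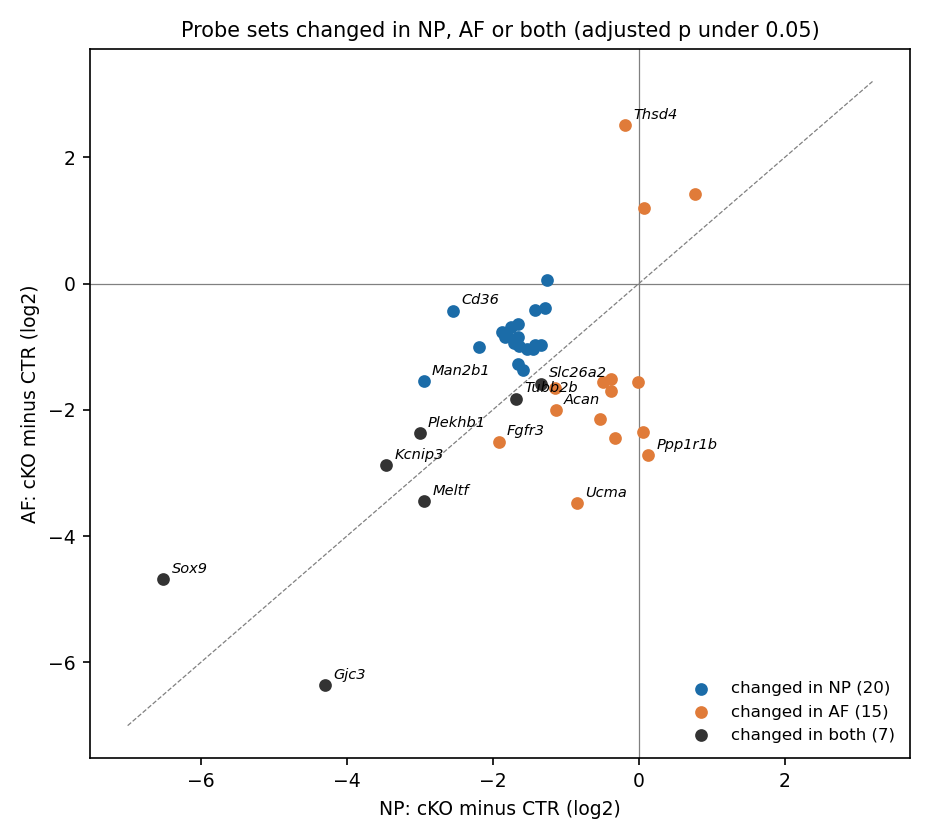
Log2 change from CTR to cKO in the NP (horizontal axis) and AF (vertical axis) for the 42 probe sets that changed in NP, AF or both, with a dashed line where the changes are equal. The 7 genes that fell in both include Sox9 at -6.51 and -4.68 and Gjc3 at -4.30 and -6.36.

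Whether the response differs between the compartments was tested as the NP change minus the AF change. In limma no probe set passed an adjusted p of 0.05 (0 of 22206, smallest adjusted p = 0.106), while 1496 had an unadjusted p under 0.05 and 977 passed the thresholds of the labels, 496 higher and 481 lower. The smallest p was that of Ppp1r1b, at 2.84 (SE 0.45, unadjusted p = 4.8e-06), which was -2.71 in the AF and 0.13 in the NP. Its NP signals of 5.35 and 5.48 lie under the negative control medians per array, which reach 6.59. An NP fall could therefore not be seen, and the difference restates its AF fall. Among the 10 smallest p, none of which passed, were also Osbpl8 (-1.54, SE 0.27), Scin (2.12, SE 0.43), Thsd4 (-2.70, SE 0.55), Ube2u (1.35, SE 0.28), Srgn (-1.40, SE 0.31), Baiap2 (-1.51, SE 0.34), Adgrg6 (2.40, SE 0.55), Car1 (-2.66, SE 0.61) and Scgb1b27 (1.24, SE 0.29). Thsd4 lies under the negative controls in the NP, and Ube2u and Scgb1b27 in all 4 groups. For Sox9 the difference was -1.83 (SE 0.43, unadjusted p = 4.3e-04, adjusted p = 0.667). The count of 0 became 1 without AF CTR replicate 1, 1 without AF CTR replicate 2 and 3 without AF CTR replicate 3. Each of the 2 pairs of AF arrays left out above also gave 1.

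As groups, the fall of cartilage matrix and Sox9 target genes was smaller in the NP than in the AF (median difference 0.83, adjusted p = 1.9e-04), with adjusted p = 0.565 with an estimated correlation. In NP CTR, 12 of the 30 members lie under the negative controls and have no room to fall, Matn3, Mia and Ucma among them, so part of this difference is set by the background. Over the other 18 members, chosen after seeing the data and not tested, the median change was -0.62 in the NP and -1.27 in the AF. The NP changes include NP cKO replicate 4, whose mean list signal of 9.37 lay above all NP CTR arrays and lessens the NP fall. Without that array the adjusted p of the list difference was 0.0158, the highest among the 16 omissions of 1 array. The differences of neutrophil markers (-1.94, adjusted p = 1.4e-11), skeletal muscle markers (-1.18, 1.1e-07), cell cycle genes (-0.55, 2.1e-06) and erythroid markers (-0.56, 9.1e-04) were negative, with a larger rise in the AF, and all had adjusted p of at least 0.565 with an estimated correlation. So were those of macrophage markers (-0.36, 0.00252), cholesterol synthesis (-0.33, 0.00327), p53 targets (-0.32, 0.010), endothelial markers (-0.37, 0.0183) and autophagy genes (-0.17, 0.0408), with adjusted p from 0.565 to 0.677 with an estimated correlation. Epidermal keratinocyte markers differed by 0.34 (adjusted p = 0.0450, adjusted p = 0.565 with an estimated correlation). The muscle call was lost, with its sign turned, without AF cKO replicates 2 and 4 (adjusted p = 0.482). Those of autophagy (0.395), keratinocyte (0.0575) and p53 genes (0.0673) were lost too, with their signs kept. Without AF CTR replicate 1 and AF cKO replicate 3 the autophagy (0.0824) and keratinocyte calls (0.0743) were lost. A second quantile normalization ended the same pair (0.516 and 0.115), and the filter on dim probe sets ended these and the calls of p53, macrophage and endothelial genes (0.117, 0.0914 and 0.341). Leaving out 1 array ended the autophagy call for 9 of 16 arrays, the keratinocyte call for 9 and the endothelial call for 5 (adjusted p up to 0.274, 0.183 and 0.183). It ended the macrophage call without AF CTR replicate 3 (0.0682) or AF cKO replicate 3 (0.0753).

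In control mice, NP and AF differed far more than cKO and CTR did. No gene list was tested for this comparison. The 10 genes with the largest difference toward the AF included several of the matrix, with differences (NP minus AF, log2) of -9.89 for the collagen gene Col1a2 (SE 0.58), -10.17 for Dcn (SE 1.74), -12.40 for the cartilage protein gene Chad (SE 1.03), -10.28 for Cnmd (SE 0.86), -10.59 for Cytl1 (SE 0.99) and -9.94 for the bone sialoprotein gene Ibsp (SE 0.50). Clec3a (-12.18, SE 0.92), the matrix proteins Thbs1 (-10.75, SE 0.56) and Vcan (-10.21, SE 1.23) and the BMP antagonist Grem1 (-10.09, SE 0.69) complete the 10. Genes higher in the NP included Egln3, an oxygen-sensing hydroxylase (2.89, SE 0.45), the methyltransferase Inmt (3.31, SE 0.64), Rgs9bp (3.21, SE 0.37), the desmosomal Perp (2.88, SE 0.34), the receptors Chrm2 (2.79, SE 0.41) and Tacr1 (2.73, SE 0.55), Zbtb8b (2.85, SE 0.62), Frmd5 (2.82, SE 0.38), Ranbp3l (2.76, SE 0.42) and Plcl1 (2.72, SE 0.36). All 20 had adjusted p of at most 0.00299. The NP signals of Chad (6.64), Clec3a (6.04), Thbs1 (4.51), Cnmd (6.03) and Ibsp (6.93) lie at or near the background, where the negative control medians per array reach 6.59. These differences are therefore lower bounds and the order of sizes carries no meaning. Sox9 itself was at 16.27 ± 0.36 in the NP and 16.92 ± 0.51 in the AF (-0.65, SE 0.30, adjusted p = 0.141).

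In total 4462 probe sets differed at an adjusted p under 0.05 between NP and AF of control mice, 2211 higher in the NP and 2251 higher in the AF, and 3775 of them had non-overlapping groups, which chance gives in 2.86% and which held for 22.6% of all probe sets. Array medians were lower in the NP than in the AF by a mean of -0.13, and after centring each array on its median 5062 differed, 3293 higher in the NP and 1769 higher in the AF. All 20 genes named above kept their calls and directions after centring.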

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

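Apart from the count of list calls in other splits, the tests below were chosen, or the rules for reading them rewritten, only after seeing the result. A gap test singled out 4 of 136 groups of 4 arrays, where chance flags about 1 in 20 groups, here 6.8. In NP CTR replicate 3, Cd36 was 10.82 (the others 9.68 to 9.78), Dcn was 10.65 (6.18 to 6.86) and the mean of the hypoxia and glycolysis genes was 13.74 (13.25 to 13.33). In AF cKO replicate 3, Fgfr3 was 11.48 (10.76 to 10.87).

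A difference between compartments in the response to the knockout was found for 11 lists by the camera test of the difference. The adjusted p was 1.4e-11 for neutrophil markers, 1.1e-07 for muscle markers, 2.1e-06 for cell cycle genes, 1.9e-04 for cartilage genes, 9.1e-04 for erythroid markers and 0.00252 for macrophage markers. It was 0.00327 for cholesterol synthesis, 0.010 for p53 targets, 0.0183 for endothelial markers, 0.0408 for autophagy genes and 0.0450 for keratinocyte markers. None held with an estimated correlation.

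The counts were set against the 35 splits of the animals, or of the control arrays for the tissues. The number of counts compared was not corrected for. For the 27 NP calls no other split called any (1 split, at most 0 elsewhere). That is the lowest share that 35 splits can give, and the 27 include Sox9, the targeted gene. The overlap of 7 (1 split, at most 0 elsewhere) adds nothing to this, since without NP calls the other splits had none to share. The 4462 tissue calls were set against splits of the 8 control arrays (1 split, at most 1 elsewhere), which treat the NP and AF arrays of 1 animal as separate. Chance is not excluded for the 22 AF calls, which were reached in 2 splits, with 365 in the other. That split exchanges AF CTR replicate 1 and AF cKO replicate 4 and points to a structure of the samples. Its sides separate on the mean neutrophil signal, with 9.77 to 11.21 against 6.06 to 8.18. They also separate on that of macrophage markers, with 7.75 to 8.38 against 6.37 to 6.85. The split is thus not a grouping free of structure, and the cause of its 365 calls was not tested. Nor is chance excluded for the 1496 probe sets of the difference (10 splits, up to 2555), for the correlation of 0.157 (7 splits, up to 0.382) or for the 32 list calls (10 splits, up to 48).

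For the markers of other cells in the AF of cKO mice, whether marrow or blood was carried over in amounts unrelated to genotype stays open: the neutrophil score gave an exact permutation p of 0.0571, which shows neither a relation nor its absence, and AF CTR replicate 1 lay in the cKO range. The exact permutation p of the other AF lists tested was 0.0571 for cartilage, 0.114 for erythroid, 0.143 for cell cycle, 0.229 for macrophage and muscle, 0.6 for lymphocyte and 0.686 for osteoclast genes, and none was under 0.05. For mature neutrophils entering from blood, the score of granulocyte precursor genes, which are made in marrow, was higher by 1.97 (exact permutation p = 0.229). That test compares genotypes and cannot tell blood from marrow. The precursor score was 8.47 in AF CTR replicate 1 and 7.56, 8.01 and 11.67 in AF cKO replicates 1 to 3. These arrays also had the highest neutrophil signals, and the values argue against mature neutrophils alone in them. In AF cKO replicate 4 (6.19) and the other AF CTR arrays (5.53 to 5.81) the score lay under the negative controls. There the question stays open. Whether muscle was carried over in some dissections stays open: of the 26 muscle genes, 24 were highest in AF cKO replicates 2 and 4, which restates the pattern, since these genes vary together.

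The genes Gjc3 and Plekhb1, known from glia, fell in NP and AF. Whether there were fewer myelinating glia stays open, and the rule for reading Mbp, the myelin basic protein gene, was rewritten several times with the values known and gave different answers. In 3 of 4 AF CTR arrays and 1 of 4 NP CTR arrays, Mbp lay below and Gjc3 and Plekhb1 above all cKO arrays of the compartment. Mbp was 15.77, 6.93, 6.73 and 6.61 in AF CTR replicates 1 to 4 and 8.61 to 13.16 in AF cKO, so the groups overlap, and in the NP most Mbp values lie near the background. The nerve and Schwann cell list was not called in the NP (adjusted p = 0.657) or the AF (adjusted p = 0.382), and no biological explanation was tested.

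All 27 NP calls are falls. A shift of the array medians does not explain this, since after centring 26 fell and 0 rose. Centring moved the NP changes by only 0.0219, so this outcome was near certain. The medians lie near the background, so a shift among brighter genes alone was not tested. Whether a larger spread between animals in rising genes explains the lack of rises stays open. The median residual SD of the 74 rises over that of the 188 falls past the thresholds of the labels was 1.49. These sets were chosen by p and fold, and over all probe sets the ratio was 1.01.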

How the results depend on the processing

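Of 50 called gene results, 29 kept their call and direction under every alternative, 36 under every omission of 1 array, and none reversed. The 50 include the 10 genes per direction named for NP against AF in CTR, which all kept their calls under every alternative. Of the genotype results among the 50, few did so. These were Gjc3, Kcnip3, Plekhb1, Meltf, Cd36, Tmod2 and Dhrs3 in the NP, and only Gjc3 and Meltf in the AF. Sox9 ranged from -6.64 to -6.34 in NP and from -4.93 to -4.38 in AF. Leaving out 1 array gave 10 to 19 NP calls, 12 to 142 AF calls, 0 to 3 calls for the difference and 3552 to 4160 for the tissues, and leaving out 1 replicate number of every group gave 3 to 6 shared genes. The thresholds of the labels gave 262, 774 and 977 calls and 78 shared genes. A second quantile normalization gave 37 AF calls and 1 for the difference, and the cause was not tested. The 8 AF arrays alone gave 8, and the filter on dim probe sets 2663 tissue calls, with fewer genes tested. Without AF cKO replicates 2 and 4, chosen after seeing the data, 34 AF and 1 difference calls were found, and without AF CTR replicate 1 and AF cKO replicate 3, chosen likewise, 112 and 1, with fewer samples. The 32 list calls became 0 with an estimated correlation and 0 with fry.

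The sign turned for genes without a call when 1 NP array was left out, over ranges of -0.0215 to 1.19 for Slc6a12, -0.0629 to 0.230 for Calcr, -0.116 to 1.26 for Atp6v0d2, -0.855 to 0.0288 for Retnlg and -0.146 to 1.09 for Ramp2. Without AF cKO replicates 2 and 4, Myh8 (-0.0111) and Des (-0.218) turned, as did the muscle list for the difference (adjusted p = 0.482), and Ihh (0.00342) turned without AF CTR replicate 1 and AF cKO replicate 3. The correlation across genes ranged from -0.0638 to 0.218 when 1 replicate number was left out. The cause was not tested.

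CTR and cKO mice share only a replicate number: same-numbered arrays correlated with r from -0.275 to 0.208 and 3 of 8 correlated best with their own number, a hint from the data and not the design. With the number as a replicate block 26 NP and 20 AF probe sets were called, and 21 and 4 in the 8 arrays of each tissue. With the animal as a fixed block the difference gave 0 and the tissues 4175. Negative controls with medians up to 6.59 lie close to the median probe set mean of 6.76, so changes in dim genes are limited by background.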

Other observations

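Markers of the notochord-derived cells of the NP were not called as a group in either compartment. Krt19, a keratin of these cells, was at 18.09 in NP CTR and 18.18 in NP cKO (0.09, SE 0.32). Its signal was also high in the AF, from 15.35 to 16.42 in CTR and from 15.41 to 17.34 in cKO. The mean signal of the list was 11.23 in NP CTR and 11.26 in AF CTR, so this list does not tell the compartments apart. How much of the AF signal comes from NP cells was not tested. Krt8, another keratin, changed by -0.99 (SE 0.32) with an adjusted p of 0.684. When adjusted over this list alone in the AF, Car12, a carbonic anhydrase, was lower (-2.85, SE 0.70, to 5.65 in cKO, under the negative controls), Shh, a signalling protein of the notochord, was lower (-0.64, SE 0.20), and Cd44, the hyaluronan receptor, was higher (1.65, SE 0.49).

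In NP cKO replicate 4, Prg4 was 15.35, against 8.35, 10.42 and 10.06 in replicates 1 to 3. The mean signal of the cartilage list was 9.37 in that array and at most 8.44 in the other NP cKO arrays. Mbp was 15.77 in AF CTR replicate 1, and 6.93, 6.73 and 6.61 in the other AF CTR arrays. The mean of the granulocyte precursor genes was 11.67 in AF cKO replicate 3 and 8.47 in AF CTR replicate 1.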
